A study of Mus musculus with 8 samples.

How the data were processed

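RNA from gonadal white adipose tissue of mice aged 10 weeks was measured on Affymetrix mouse expression arrays, 1 array per sample. Per the labels, 4 arrays came from control mice and 4 from mice in which Pex5 had been deleted under the aP2 promoter. RNA was extracted with Trizol, amplified and labelled with biotin on a robotic workstation, per the labels' protocols. Per the submitters' processing notes, the values were made with RMA, which corrects background, normalises between arrays and summarises the probes of a probe set; its version is not given in the sources used here. The deposited values are on the log2 scale: they ran from 2.71 to 14.8 over the 45037 probe sets used. The deposited table holds no detection calls, so the background level of a probe set is not known from it. Values near the lower end may be compressed by this processing, which makes a change of a dim gene look smaller.

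The table has 45101 probe sets on 8 arrays. The 64 Affymetrix control probe sets were left out of the tests and kept for measures of RNA and array quality. In the platform annotation, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none; none was named from a probe set with several symbols. Symbols were matched by Entrez number to a table of RefSeq genes on assembly GRCm38.p6, which listed 34741 of those with 1 symbol and changed 0 of them. The annotation dates from 2016. The same table was used only to find neighbouring genes. Each gene was represented by the probe set with the highest mean over the 8 arrays, giving 18193 genes, of which 9010 had more than 1 probe set. In 4232 of these the probe sets differed in the sign of the difference between groups.

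Knockout was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are knockout minus control on the log2 scale, with intervals of 95% that are not adjusted for the number of genes. Gene lists were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the 33 lists with at least 5 measured genes. A 34th list, of sex-linked genes, was too short. Of 710 list members, 646 were measured under a usable name; the others were not analysed here. A list's score on an array is the mean of its members after subtracting each member's mean over the 8 arrays, and scores were compared by a two-sided exact permutation test over the 70 arrangements, whose smallest possible p is 0.0286. With 4 arrays per group, the number of arrays limits the precision. The labels do not say whether arrays of a group came from separate animals, so p-values measure the spread between these samples.

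The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Pex5, then up to 10 genes in each direction past the threshold with complete separation of the groups and a higher group's mean above the median of all genes; where fewer passed, the next by unadjusted p filled up to 5. It also named up to 4 members of each list past the threshold or, where none passed, the 2 with the smallest unadjusted p. Symbols that only number a clone were passed over. Alternatives were a variance trend with robust estimation, a filter on dim genes, renormalisation, the mean of a gene's probe sets, every probe set alone, array weights, a plain test per gene, other thresholds and leaving out each array. Chosen after seeing the data were the adjustments for a split of the arrays and for RNA quality, leaving out 3 arrays, the exact test of list scores, estimated correlations within the other alternatives, and 7 short lists of markers of other tissues and cells (liver, seminal vesicle, spermatid, caput epididymis, corpus and cauda epididymis, ciliated epithelium, neutrophil). RNA quality was taken as the difference between the 3' and 5' control probe sets of pyruvate carboxylase. The split put arrays in 2 sets of 4 at the widest gap in the lower quartile of each array's values.

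The steps were tested on simulated data for 18193 genes, 4 arrays against 4, drawn with the real means and spreads and no structure between arrays. Of 50 genes changed at each fold size, the limma step called 24 at 1.5-fold, 42 at 2-fold, 44 at 3-fold and 49 at 4-fold, with 14 false calls. In a simulation with 1 list shifted, camera with the preset correlation called 2 of 33 lists, the shifted list among them. Genes were drawn independently there. In the real data the estimated correlation was 0.73 in the interferon list and 0.09 in the ovary, oviduct and uterus list. The simulation therefore does not test the preset on correlated genes. Figures were drawn with matplotlib 3.10.9.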

Results

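Gonadal white adipose tissue of mice aged 10 weeks was profiled on 8 arrays, 4 from controls and 4 from aP2-Pex5 knockouts on a Swiss background. Pex5 is the receptor that imports enzymes into the peroxisome, and the knockouts were described by the submitters as lacking working peroxisomes in fat. The comparison asks which transcripts of this tissue differ when adipose peroxisomes are missing. Arrays are named by group and by the replicate number on the label, 1, 2, 3 and 4 for control and 6, 8, 9 and 10 for knockout. The median log2 value per array ran from 6.45 to 6.52. The tissue expressed adipocyte genes at high level in both groups, with leptin (Lep) at 12.55 in control and 13.07 in knockout.

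The Pex5 signal was the same size in both groups. Probe set 1426770_at read 9.38 ± 0.24 in control and 9.36 ± 0.10 in knockout (SD, n = 4 each), a difference of -0.01 with a 95% interval of -0.29 to 0.26 and an adjusted limma p of 0.999. Probe set 1422063_a_at read 9.03 ± 0.35 and 9.06 ± 0.23, a difference of 0.04 with an interval of -0.39 to 0.46. On the arrays labelled knockout, 1426770_at lay between 9.27 and 9.50, inside the control range of 9.06 to 9.58. The labels do not state which exons were deleted or where these probes lie, so the probe sets cannot check the genotype labels, and the tissue also holds cells other than adipocytes.

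**Figure D1:**
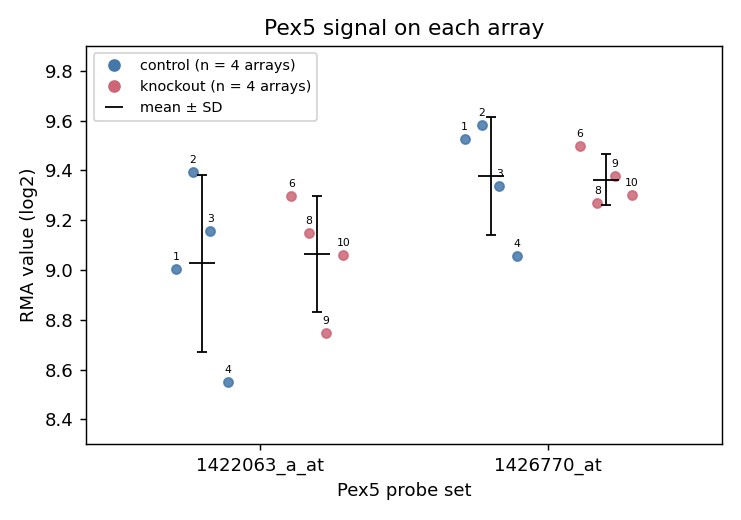
RMA value (log2, y axis) of both Pex5 probe sets (x axis) on each of the 8 arrays, points numbered by replicate, with mean ± SD per group (n = 4). The groups overlap on both probe sets, with means of 9.38 and 9.36 on 1426770_at and 9.03 and 9.06 on 1422063_a_at.

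No transcript passed the test between knockout and control. Of 18193 genes, 0 had a limma adjusted p under 0.05, and the smallest was 0.999. At an unadjusted p under 0.05 there were 466 genes, 215 higher and 251 lower in knockout, or 2.56% where chance gives 5%. A plain test per gene also called 0, with 511 at an unadjusted p under 0.05, and limma on every probe set called 0 of 45037, with 1139. The groups were completely separated in 310 genes, 1.70%, against 2.86% by chance. The median half-width of the 95% interval of a gene was 0.25.

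Among genes of moderate or high level, the smallest unadjusted p-values on the higher side belonged to Prkag3, Trib3, Cdkn1c, Epn2 and Myo1d. Prkag3, a regulatory subunit of AMP-activated protein kinase, read 7.11 ± 0.24 in control and 7.69 ± 0.15 in knockout, a difference of 0.58 (95% interval 0.28 to 0.89). Trib3, a pseudokinase induced by the integrated stress response, read 7.44 ± 0.07 and 7.91 ± 0.22, a difference of 0.47 (0.22 to 0.73). Cdkn1c, the cell cycle inhibitor p57, differed by 0.60 (0.27 to 0.93), Epn2 by 0.34 and Myo1d by 0.28. On the lower side stood Ces1f, a carboxylesterase, at 9.60 ± 0.41 and 8.84 ± 0.14, a difference of -0.75 (-1.19 to -0.32). The vitamin transporter Slc5a6 differed by -0.67, the metalloprotease Adamts12 by -0.62, Kctd12b by -0.39 and the sialyltransferase St3gal4 by -0.30. Complete separation of the groups was part of the rule that picked these 10 genes, and none passed, with a limma adjusted p of 0.999 for each.

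**Figure D2:**
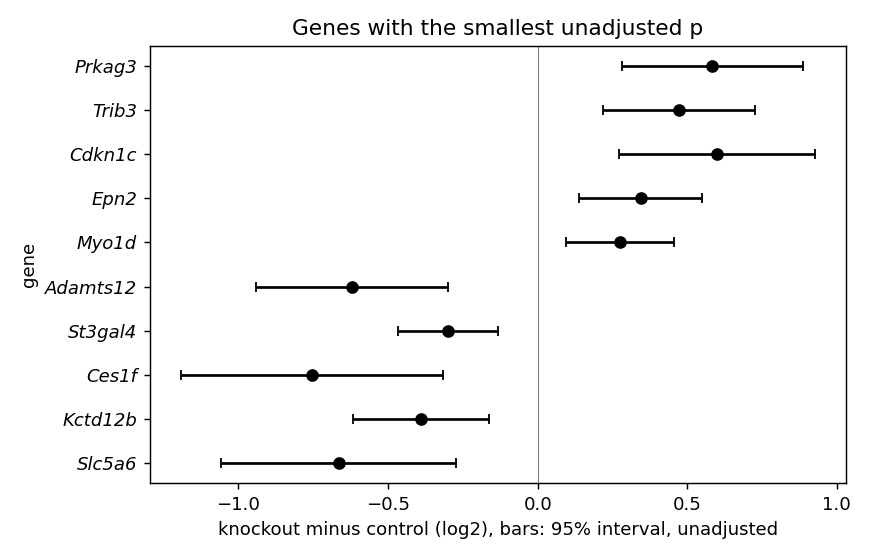
Difference between knockout and control (log2, x axis) for the 10 genes (y axis) with the smallest unadjusted p among separated genes of moderate or high level; bars are 95% intervals, not adjusted for 18193 genes. Differences run from -0.75 for Ces1f to 0.60 for Cdkn1c.

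Most genes of the peroxisome and of the ether lipid list lay slightly below control. None of these lists passed over the 8 arrays with equal weights and no covariate. Of 13 measured genes of peroxisome biogenesis 12 were lower (median -0.05; camera adjusted p = 0.144), with Pex6, which recycles Pex5, at -0.38 and Pex3 at -0.18. Of 46 peroxisomal enzymes 30 were lower (median -0.07, adjusted p = 0.144); Lonp2, the peroxisomal protease, stood at -0.25 and the bifunctional beta-oxidation enzyme Ehhadh at -0.49. The mean over the enzymes was -0.00272 and the exact permutation p of their score 0.971, since Dao (1.34), Slc27a2 (1.04) and Pipox (0.96), picked after their values were seen, lay higher. Of 11 genes in the ether lipid list 8 were lower (adjusted p = 0.192), Cept1 at -0.24 and Lpcat3 at -0.22. No member of these lists passed over all genes or adjusted over the list alone, where the counts were 0 for each. At an unadjusted p under 0.05 the counts were 1, 5 and 0. The biogenesis and enzyme lists passed with array weights (0.00411 and 0.00963), without control 4 (4.21e-05 and 0.00275) and without knockout 6 (0.0186 for each), the enzymes also without control 3 (0.00308) and ether lipid genes without knockout 6 (0.0429). Chosen after seeing the data, an RNA quality covariate (median -0.10, 0.00760), that covariate with the array set (-0.08, 0.0249) and leaving out controls 1 and 4 and knockout 9 (-0.17, 0.0319) also put the biogenesis list past the threshold. None of these calls held with an estimated correlation (adjusted p = 0.745 or more). Over the fits that left out 1 array the biogenesis median ran from -0.18 to -0.00159, the latter without control 2 (0.740), and was -0.02 without control 1 (0.539). The enzyme median was -0.03 without control 2 (0.664) and -0.02 without control 1 (0.685), where the camera direction turned to higher. The arrays fall into 2 sets by their value distributions, controls 1 and 2 with knockouts 6 and 8, and controls 3 and 4 with knockouts 9 and 10. Within the latter set the medians of the biogenesis and enzyme lists were 0.02 and 0.02, within the former -0.17 and -0.15, where both lists passed (camera adjusted p = 0.000777 for each, 2 arrays per group; adjusted p = 0.654 and 0.830 with an estimated correlation).

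Of 4 lists past the camera threshold, the lipogenic list was the one of adipocyte metabolism. Of 27 genes of lipogenesis and triglyceride synthesis, 22 were lower in knockout (median -0.18, adjusted p = 0.0126 with the preset correlation; adjusted p = 0.978 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Mogat1, which makes diacylglycerol, differed by -0.47 and Acaca, the enzyme of the committed step of fatty acid synthesis, by -0.86. The call was lost without control 1 (median -0.04, adjusted p = 0.539), control 2 (-0.11, 0.223), knockout 9 (-0.17, 0.102) or knockout 10 (-0.11, 0.416). It was also lost when array medians were subtracted (-0.20, 0.0503) or a gene's probe sets averaged (-0.13, 0.0527), and the median was -0.36 without control 4. Control 1 had the highest score of this list, 0.52, and also liver markers at 10.40 and a difference between 3' and 5' probe sets of pyruvate carboxylase of 3.97. The median was -0.36 within the set of controls 1 and 2 and knockouts 6 and 8, and 0.01 within the other set, where it did not pass (adjusted p = 0.414).

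Mitochondrial lists leaned lower by small amounts, with 15 of 21 fatty acid oxidation genes (Acad11 -0.13, Hadha -0.20), 37 of 48 respiratory chain genes (Ndufb5 -0.17, Cycs -0.15) and 16 of 20 genes of the tricarboxylic acid cycle (Pdha1 -0.27, Pcx -0.38) below control, each at a camera adjusted p of 0.144. With the array set as a block these 3 lists passed, at 0.0478, 0.0484 and 0.0478 (adjusted p = 0.873, 0.940 and 0.873 with an estimated correlation). They also passed with array weights (0.00513, 0.000740 and 0.00209) and without control 3, control 4 or knockout 6 (at most 0.0364), and the respiratory chain without knockout 8 (0.0301), all lost with an estimated correlation (adjusted p = 0.745 or more). Without control 1 the medians of the 3 lists were -0.0123, 0.0113 and 0.00632, and without control 2 -0.00238, -0.00123 and -0.00351 (camera adjusted p at least 0.539). The camera direction turned to higher for the respiratory chain in both fits and for the cycle without control 1. Within the set of controls 1 and 2 the medians were -0.19, -0.18 and -0.24 (4.51e-06, 2.70e-10 and 1.22e-08; adjusted p = 0.654, 0.426 and 0.654 with an estimated correlation). Within the set of controls 3 and 4 the respiratory chain and cycle lists ranked higher in knockout, with medians of 0.08 and 0.09 (0.000117 and 0.0343; adjusted p = 0.803 for each with an estimated correlation). Of 26 adipocyte identity genes 19 were lower (adjusted p = 0.439), with Lep at 0.52 and Slc2a4, the insulin-responsive glucose transporter, at -0.17. Of 20 cholesterol synthesis genes 13 were lower (0.843; Srebf2 0.18, Hsd17b7 0.16), of 20 lipolysis and adrenergic genes 7 (0.805; Npr3 0.26, Adcy5 0.26), and of 16 glycolysis and glucose uptake genes 12 (0.210; Irs1 -0.33, Pkm -0.22). In the list of brown and beige adipocytes 13 of 23 were higher (0.321); Prdm16 read 0.58 and Elovl3 -0.62. Without control 4 the adipocyte identity (0.00182), cholesterol (0.00173) and glycolysis (0.0446) lists passed, and glycolysis also without control 3 (0.0445) or knockout 6 (0.0369). Within the set of controls 1 and 2 these 3 lists passed at medians of -0.08, -0.25 and -0.15 (0.00732, 2.43e-06 and 0.0305), and adipocyte identity passed without controls 1 and 4 and knockout 9 (-0.15, 0.0319). These calls were all lost with an estimated correlation (adjusted p = 0.654 or more). Over the fits that left out 1 array the medians ran from -0.09 to -0.00914 for adipocyte identity, from -0.28 to 0.03 for cholesterol and from -0.11 to 0.000260 for glycolysis. Without controls 1 and 4 and knockout 9, a choice made after seeing the data, Elovl3 passed at -0.86 (adjusted p = 0.0438), with 6.05 in the kept controls, 5.47 in the left-out ones and 5.14 over the knockouts.

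Stress and growth lists did not pass over the 8 arrays either. Of 22 unfolded protein response genes 13 were higher (adjusted p = 0.192; Trib3 0.47, Atf4 0.20), of 21 NRF2 and antioxidant genes 11 (0.812; Hmox1 -0.27, Cat -0.13), of 25 proliferation genes 7 (0.372; Aurkb -0.22, Ccna2 -0.32), of 28 extracellular matrix genes 15 (0.843; Mmp12 -1.45, Loxl1 0.30), of 19 immediate early genes 7 (0.470; Atf3 -0.28, Jun 0.23) and of 17 clock genes 10 (0.675; Hlf 0.26, Per2 0.27). Mmp12 read 7.25 and 6.33 in knockouts 9 and 10 but 9.16 and 9.92 in knockouts 6 and 8, against 9.08 to 9.82 in controls. Proliferation genes passed without control 3 (0.00167) or knockout 6 (0.0196) and immediate early genes without control 2 (0.0197) or knockout 8 (0.0167), all lost with an estimated correlation (adjusted p = 0.745 or more). Over the fits that left out 1 array their medians ran from -0.19 to 0.02 and from -0.18 to 0.00199. Extracellular matrix genes passed in opposite directions within the sets, at a median of 0.05 (0.0350) with controls 1 and 2 and -0.08 (0.00887) with controls 3 and 4, where immediate early genes passed too (-0.13, 0.00620). These calls were lost with an estimated correlation (adjusted p = 0.830, 0.585 and 0.585).

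Interferon response genes and macrophage markers ranked lower in knockout than other genes. All 19 interferon response genes were lower (median -0.28, camera adjusted p = 9.66e-06; adjusted p = 0.978 with an estimated correlation), Gbp2, a guanylate-binding protein, by -0.44 and Usp18 by -0.35. Control 4 stood apart, with a list score of 0.74 where the other controls lay between -0.13 and 0.04, and without it the median was -0.09 and the call was lost (adjusted p = 0.249), as it was without controls 1 and 4 and knockout 9 (-0.11, 0.379). Control 4 also had neutrophil markers at 8.87, a red blood cell score of 1.24 and a difference between 3' and 5' probe sets of pyruvate carboxylase of 4.83. Of 28 macrophage markers 26 were lower (median -0.25, adjusted p = 9.66e-06; adjusted p = 0.978 with an estimated correlation), Adgre1, a surface receptor of mature macrophages, by -0.44 and Cd68 by -0.37. Knockout 6 had a macrophage score of -0.42, the other knockouts between -0.07 and 0.06; the median was -0.11 without knockout 6 (adjusted p = 0.0186) and -0.16 without control 3 (0.00615), and the list passed without each array in turn. Knockout 6 was also low in the scores of mesothelial (-1.03), fibroblast (-0.26), T and NK cell (-0.29) and B cell (-0.21) markers. Control 3, with the highest macrophage score (0.36), was also high in mesothelial (0.50), fibroblast (0.28) and endothelial (0.25) markers. The scores of these lists overlapped between groups, with two-sided exact permutation p-values of 0.286 and 0.229 (1 for each after Benjamini-Hochberg adjustment over the lists), and 0 members of either passed over all genes or adjusted over the list alone. Within the sets of controls 1 and 2 and of controls 3 and 4, the median was -0.27 and -0.34 for interferon genes and -0.11 and -0.31 for macrophage markers, which did not pass in the former set (adjusted p = 0.420). Inflammatory mediators did not pass (0.519), with Tgfb1 at -0.22 and Il1b at -0.39.

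Markers of the other cells of fat did not pass over the 8 arrays with equal weights and the deposited normalisation. The adjusted p was 0.963 for T and NK cells (Il7r -0.32, Gzma -0.44), 0.888 for B and plasma cells (Fcrla -0.21, Cxcr5 -0.12), 0.843 for endothelium (Gpihbp1 0.18, Ramp2 0.06), 0.0779 for smooth muscle and pericytes (Lmod1 0.34, Cnn1 0.66), 0.594 for mesothelium (Krt19 0.44, Lrrn4 -0.70), 0.964 for Schwann cells and sympathetic nerve (Npy -0.87, Gap43 -0.10), 0.769 for skeletal muscle (Mb 0.22, Pvalb 0.14) and 0.871 for red blood cells (Hba-a1 -0.17, Hba-a2 0.16). Smooth muscle markers (median 0.06) passed with array medians subtracted (0.04, adjusted p = 0.0288), with array weights (0.18, 0.00411), without control 3 (0.18, 0.00615) and without control 4 (0.19, 0.00173). Over the fits that left out 1 array their median ran from 0.03 to 0.19. It was 0.48 within the set of controls 1 and 2 (7.08e-06), -0.01 within the other set, and 0.15 without controls 1 and 4 and knockout 9 (0.0319). None of these 6 calls held with an estimated correlation (adjusted p = 0.982, 0.891, 0.745, 0.384, 0.426 and 0.971). Endothelial markers passed in opposite directions within the sets, at 0.21 (0.000111) with controls 1 and 2 and -0.21 (4.59e-06) with controls 3 and 4, and mesothelial markers at -0.90 (0.0305) with controls 1 and 2. These calls too were lost with an estimated correlation (adjusted p = 0.830, 0.569 and 0.830). Cnn1 passed at 1.45 (adjusted p = 0.0496) without controls 1 and 4 and knockout 9, a choice made after seeing the data. The left-out controls averaged 7.52, near the 7.51 of the knockouts, and the kept controls 6.18. In the list of fibroblasts and preadipocytes (0.843; Pi16 0.44), Dlk1, an inhibitor of adipocyte differentiation, read 5.98 ± 0.07 in control and 5.50 ± 0.18 in knockout, lower on 4 of 4 arrays. It differed by -0.48 and passed at a limma p of 0.0192 adjusted over the list alone, the 1 member of any list to do so. It did not pass over all genes (0.999). With 34 lists each adjusted alone at 0.05, 1 such call is no more than chance would give.

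Genes of neighbouring organs differed between arrays more than between groups. The list of ovary, oviduct and uterus markers ranked higher in knockout (12 of 14 higher, median 0.14, camera adjusted p = 7.42e-04; adjusted p = 0.885 with an estimated correlation), with Pgr, the progesterone receptor, at 0.52 and Greb1, an oestrogen-regulated gene, at 1.76; Foxj1, a regulator of motile cilia picked out after its value was seen, stood at 1.11. The median was 0.16 and 0.18 within the 2 array sets, and 0.59 with dim genes filtered out, which left 5 members. Its lowest scores were -0.66 in control 3 and -0.32 in control 2, and the exact permutation p of the score was 0.114. Foxj1 read 4.91 in control 3 and 7.25 in control 2. In controls 1 and 4 it read 8.92 and 9.02, inside the knockout range of 8.01 to 9.24. Ciliated epithelium markers read 5.28 in control 3 and 6.54 in control 2, and between 7.46 and 8.29 on the other 6 arrays. Epididymis and testis markers did not pass (0.192; Adam28 0.99, Rnase10 0.99) except without knockout 6 (0.0348; adjusted p = 0.817 with an estimated correlation), and their median was -0.02 without knockout 8. Exocrine pancreas markers did not pass (0.843; Prss2 0.16, Ctrb1 -0.05). Y-linked genes were expressed on all 8 arrays, Uty at 8.50 in control and 8.32 in knockout, and their mean per array lay between 8.94 and 9.12. These values argue against female animals as the source of any sample. They cannot exclude RNA of a female animal carried into a sample, which was not tested. The call of the ovary, oviduct and uterus list is not read as tissue of those organs. Xist, the transcript of the inactive X chromosome, read 8.27 in control 1 and between 5.55 and 6.20 elsewhere, a difference between groups of -0.46 that turned to 0.19 without control 1. For 9 lists near 0 the median, mean and camera direction did not share a sign.

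**Figure D3:**
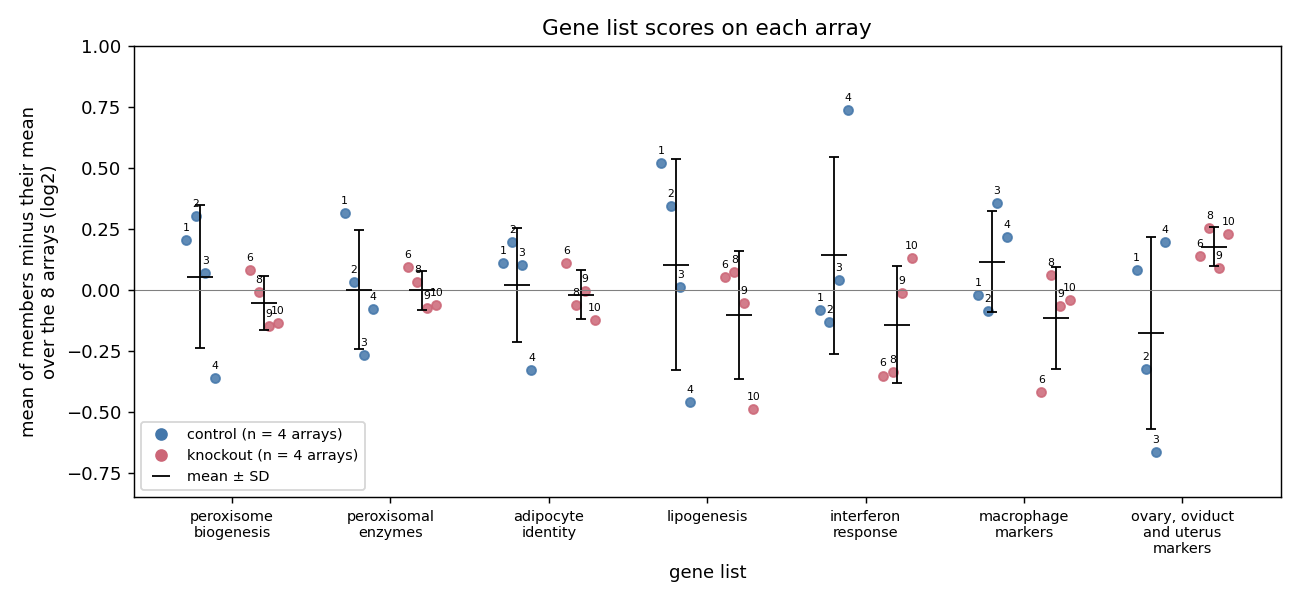
Score of 7 gene lists (x axis; mean log2 value of the members after subtracting each member's mean over the 8 arrays, y axis) on each array, points numbered by replicate, with mean ± SD per group (n = 4). Control 4 lies at 0.74 in the interferon list and control 3 at -0.66 in the ovary, oviduct and uterus list.

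Transcripts of other tissues were present on 1 or a few arrays of both groups. Liver markers averaged 10.40 in control 1 and between 5.30 and 8.08 on the other arrays, with albumin (Alb) at 13.64 in control 1 and 7.87 in control 4. Markers of the corpus and cauda epididymis averaged 9.89 in control 1, those of the caput 9.73 in knockout 8, and those of the seminal vesicle 6.80 in control 3 and 5.53 in knockout 10. Spermatid markers averaged 7.85 in knockout 9 and 7.31 in control 3, against 4.70 to 5.62 on the others. Neutrophil markers averaged 8.87 in control 4 and at most 6.35 elsewhere. None separated the groups, with exact two-sided permutation p-values from 0.257 to 0.914 over the 7 lists and an adjusted p of at least 0.84.

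**Figure D4:**
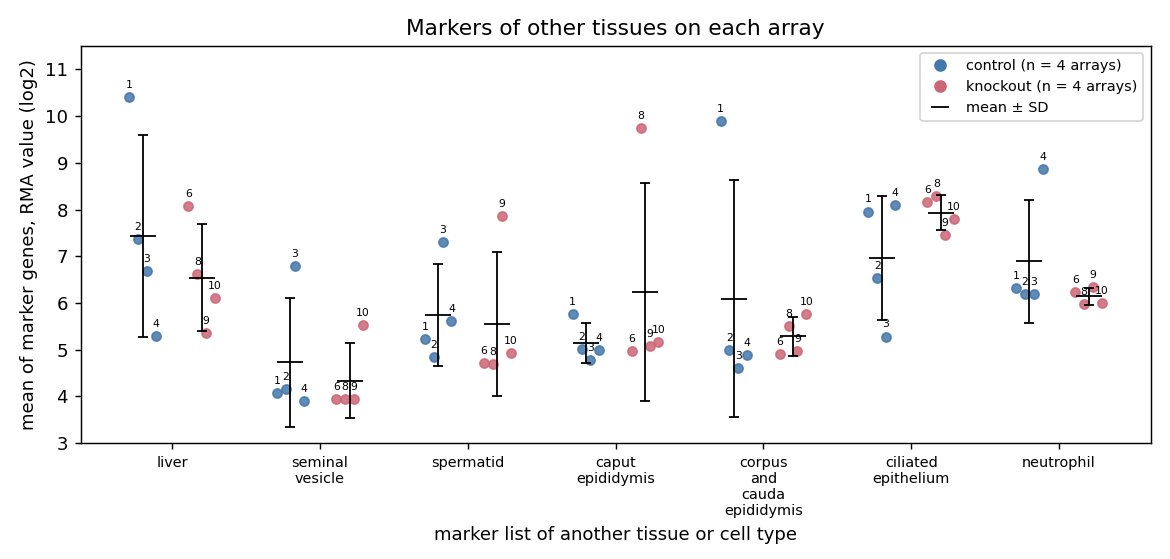
Mean RMA value (log2, y axis) of 7 marker lists of other tissues or cells (x axis) on each array, points numbered by replicate, with mean ± SD per group (n = 4). Single arrays stand apart, such as control 1 at 10.40 for liver and knockout 8 at 9.73 for the caput epididymis.

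No gene lying next to Pex5 passed. Of 209 measured genes within 10 Mb of Pex5, limma called 0, and 7 had an unadjusted p under 0.05 (3.35%, against 2.55% of the other genes; two-sided Fisher's exact p = 0.503). Within 2 Mb the count was 4 of 61 (6.56% against 2.55%, Fisher's exact p = 0.0709) and within 20 Mb 11 of 330 (3.33% against 2.55%, Fisher's exact p = 0.375). The smallest p-values belonged to Ret (0.74), Scnn1a (0.68) and Slc6a12 (0.26), which were chosen after their values were seen. With no gene called, the planned test of called genes near the locus had nothing to compare.

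Knockout arrays resembled each other more than controls did. Pairwise correlations over genes ran from 0.988 to 0.994 among knockouts, from 0.967 to 0.987 among controls and from 0.971 to 0.994 between groups; genes are not independent replicates. The first principal component held 40.0% of the variance and set control 3 apart at 52.7. The difference between 3' and 5' probe sets of pyruvate carboxylase was 3.97 in control 1, 4.83 in control 4 and 4.65 in knockout 9, and between 1.59 and 2.10 on the others. The lower quartile of values divided the arrays into a set with controls 1 and 2 and knockouts 6 and 8 and a set with controls 3 and 4 and knockouts 9 and 10. With the set as a block limma called 0 genes (703 at an unadjusted p under 0.05), with the 3'-to-5' difference as a covariate 0 (674), with both 0 (1048), and within each set alone 0 (1278 and 244). Without the 3 arrays of largest 3'-to-5' difference, a choice made after seeing the data, limma called 155 genes, 152 of them higher in the 3 remaining knockouts than in controls 2 and 3. Controls 2 and 3 had the lowest ciliated epithelium markers, 6.54 and 5.28 against 7.46 to 8.29 elsewhere, and 5 of the 10 markers were among the called genes. That marker list was chosen after the data were seen, so the overlap is a description and does not test what the called genes are. For 151 of the 152 higher genes the mean of the left-out controls 1 and 4 was nearer to knockout than to controls 2 and 3. Knockout here is the mean over all knockouts, the left-out one included. The genes were picked by their difference from controls 2 and 3, and none passed over the 8 arrays. The count is therefore largely set by that choice and is a description.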

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

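The tests of liver RNA and of animal sex below were chosen after the values were seen. Over 244 groups of 4 values, 26 held an array far from the other 3 by Dixon's criterion, 10.7% where chance gives about 1 in 20, or 5%. Some of these groups were marker lists of other tissues and cells, chosen after the data were seen. Others share genes, such as Xist and the sex-linked score. The comparison with chance is therefore a description and not a test.

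Most of the widest gaps were transcripts of other organs or cells on 1 or a few arrays. In control 1 these were Xist at 8.27 (other controls at most 5.79), the sex-linked list score at 0.62, corpus and cauda epididymis markers at 9.89 (others at most 4.99) and Npy, a neuropeptide of sympathetic nerve, at 9.54 (others at most 6.23). Caput epididymis markers stood at 9.73 in knockout 8, with Adam28 at 8.01 and Rnase10 at 8.65. Seminal vesicle markers stood at 6.80 in control 3 and 5.53 in knockout 10, spermatid markers at 7.85 in knockout 9 (and 7.31 in control 3), and neutrophil markers at 8.87 in control 4. Xist was also highest among knockouts in knockout 6, at 6.20, and knockout 9 had the largest 3'-to-5' difference of its group, 4.65.

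Single genes with 1 array apart were Myo1d (9.06, knockout 6), Pex3 (10.15, control 4), Pdha1 (12.16, knockout 9), Pcx (11.87, knockout 10), Cat (12.62, control 1), Mmp12 (9.08, control 3), Tgfb1 (8.64, knockout 6), Fcrla (4.80, control 2), Pi16 (8.94, control 4), Lmod1 (6.76, knockout 9), Krt19 (9.20, control 2) and Gap43 (4.40, knockout 8). The extracellular matrix score was lowest in knockout 8, at -0.0394.

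Control 1 carried liver transcripts, with albumin at 13.64. A sample from a female animal is argued against by the Y-linked genes, whose mean in control 1 was 0.13 above that of the other 7 arrays. All 18 of the 18 liver markers were highest in control 1, but the list was written after liver transcripts had been seen there, so this count decides nothing. Liver RNA carried into the sample may be the source, a hypothesis that stays open, as does a biological difference of this sample, which was not tested. Xist followed the liver score over the 8 arrays (Pearson r = 0.863, exact permutation p = 0.0193; Spearman rho = 0.214, exact p = 0.619), but without control 1 and knockout 6, the arrays farthest from the median, r was -0.496 (exact p = 0.369; rho = -0.886, exact p = 0.0333), so the relation rests on those arrays.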

How the results depend on the processing

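The adjustments for array set and RNA quality, the fits within each array set, the fit without 3 arrays the exact test of list scores and the estimated correlations within other alternatives were chosen after the data were seen. The count of changed genes stayed at 0 under every alternative fixed beforehand, with 283 to 1566 at an unadjusted p under 0.05 over the fits that left out 1 array and 1039 with array weights. Without the 3 arrays of largest 3'-to-5' difference it was 155, 152 higher and 3 lower, with controls 2 and 3 alone left to compare. The count of lists, 4 as reported, ran from 3 to 13 when 1 array was left out. It was 10 with array weights, 7 with the array set as a block and 5 with the RNA quality covariate, alone or with the block. It was 6 without the 3 arrays, and 15 and 8 within the sets. With estimated correlations, alone or with each other alternative, it was 0. The cause of these shifts was not tested. The exact test also gave 0. Its smallest possible p lets a list pass adjustment only if many lists are completely separated at once, so that 0 decides nothing. No direction was read from an uncalled gene that moved by less than 1 SE, nor from a list with an unadjusted p of 0.05 or more. In the set with controls 3 and 4 the sign turned for Pex5 (0.14), Pdha1 (0.000363), Cxcr5 (0.0212), Lrrn4 (0.0463), Npy (0.0142) and Pvalb (-0.0587), and the camera direction for peroxisome biogenesis (median 0.0183), peroxisomal enzymes (0.0230), fatty acid oxidation (0.0427), respiratory chain (0.0806), tricarboxylic acid cycle (0.0857) and smooth muscle (-0.0113). In the set with controls 1 and 2 the sign turned for Hsd17b7 (-0.00431), Loxl1 (-0.0832), Il7r (0.0523) and Ctrb1 (0.0883). Over the fits that left out 1 array, medians ran from -0.119 to -0.0154 for peroxisomal enzymes, from -0.119 to 0.0113 for the respiratory chain and from -0.141 to 0.00632 for the tricarboxylic acid cycle. All 3 directions turned without control 1, and that of the respiratory chain also without control 2. Xist ran from -0.72 to 0.19, the latter without control 1, and stood at 0.27 without the 3 arrays, where Npy stood at 0.0621; the cause of these turns was not tested. Of the other named genes, none passed under an alternative fixed beforehand. No paired analysis was possible because the groups share no replicate numbers. Without detection calls, signal over background could not be set for dim genes.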

Other observations

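Tests of the array sets and of probe sequence were chosen after the values were seen, while the counts of lists and of dense windows over other splits were set before theirs. Over the 35 splits of the 8 arrays into 4 and 4, 23 had at least the 466 genes of the real split at an unadjusted p under 0.05, with up to 4028 in the others. For gene lists, 33 of the 35 splits called at least as many as the 4 called by genotype, with up to 21 in the others. The other splits did not all balance the 2 array sets as genotype does, so differences between the sets enter some of their counts. Chance is not excluded for either count. The real split had 0 genes past adjusted p 0.05, which all 35 reach by construction, so that count tests nothing; the highest of the others was 2.

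Of 17 clock genes, 8 were completely separated between the 2 sets of 4 arrays. None passed adjustment, which the floor of the exact test put out of reach for 8 separated genes. In the samples with controls 1 and 2 and knockouts 6 and 8, Per2 read 8.72 ± 0.24 against 7.99 ± 0.10 in the other 4, and Per3 was higher by 0.59, Cry1 by 0.33 and Tef by 0.28. Arntl, which peaks in antiphase to the Per genes, read 7.42 ± 0.11 against 8.35 ± 0.33, with Npas2 at -0.39 and Nr1d1 at -0.47. Each of these 7 genes was completely separated (exact two-sided permutation p = 0.0286, the smallest possible, and 0.0607 after Benjamini-Hochberg adjustment over 17 genes). More of the 17 genes would have to be separated for any to pass, so the adjusted value says nothing about the size of these differences. In limma with genotype in the fit, Per2 had an adjusted p of 0.0563 over all genes. With genotype in the fit, limma called 6 genes between the sets, among them Xdh, xanthine dehydrogenase, at 1.14 and the interferon-induced Oasl2 at -0.82, with 3857 at an unadjusted p under 0.05.

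The split into these sets gave 4028 genes at an unadjusted p under 0.05, the highest of the 35 and several times the count by genotype, which points to a structure of the samples. The sets were defined after the data were seen, so this count is a description. They match the first 4 and the last 4 samples in the order in which the samples are listed, which was not used to define them. RNA degradation is argued against as the whole source, because 2 of the 4 arrays of the set with controls 3 and 4 had a 3'-to-5' difference inside the range of the other set. Labelling or hybridisation in 2 rounds stays open: the hybridisation spikes read 0.18 higher in the set with controls 1 and 2, without overlap. A different time of day or feeding at collection also stays open and could have come with it: Per1, Per2, Per3, Dbp, Tef and Hlf against Arntl, Npas2 and Clock differed by 0.96 between the sets, without overlap, but these genes had been seen before the contrast was written, so it decides nothing.

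Neighbouring probe sets on chromosome 12 held some of the smallest unadjusted p-values without passing adjustment. Myt1l, a neural transcription factor, read 3.84 ± 0.13 in control and 4.96 ± 0.27 in knockout on 1421175_at (1.12, limma adjusted p = 0.999 over all probe sets). This level lies toward the lower end of all values, which start at 2.71. Other Myt1l probe sets differed by 0.59, 0.46, 0.15 and 0.09. Adi1 next to it was 0.47 higher on 1438758_at and -0.45 on 1449076_x_at. A chance cluster is not excluded: in a permutation over the 35 splits, 2 held a window of 1 Mb to each side as dense, the real split among them. The smallest hypergeometric p of a window was 6.94e-11 in the real split and 2.71e-12 in the best other. It counts probe sets as independent. Within 1 Mb of Myt1l, the 6 probe sets at an unadjusted limma p under 0.01 were all of Myt1l or Adi1. A sequence difference under the probes, as DNA of another strain would bring, may account for the opposite signs. This stretch lies outside the 10 Mb to each side of Pex5 where neighbouring genes were counted, and its linkage to the targeted locus was not shown. Adi1 was the 1 gene within 2 Mb of Myt1l with completely separated probe sets of both signs, a pattern seen in 3 of 9010 genes with several probe sets. Adi1 had been seen before this count was made, so it decides nothing. A change of transcription in the knockout was not tested apart from this.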
